A study of Mus musculus and Homo sapiens with 121 samples.

How the data were processed

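RNA was measured in sorted human tumour cells (31 libraries), in mouse stroma (62 samples in 31 columns of counts), in lung cells sorted by IL11RA and PLXDC (12 libraries) and in single CD45+ cells (8 groups, 2 sequencing runs each). Per the labels, tumour and stroma RNA was primed with oligo-dT, amplified as whole transcriptome and made into Nextera XT libraries. Per the labels, reads were aligned with STAR 2.5.1b to GRCh37 or GRCm38 and counted with HTSeq, and the single-cell reads went through Cell Ranger 1.2 and Seurat 2.1.0. The deposited values are raw counts of reads per gene for tumour, stroma and sorted samples and raw counts of UMIs per gene and barcode for single cells, checked on the files as whole numbers without scaling.

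The authors' groups were taken from the sample labels. Each stroma column was treated as 1 animal and site. The 9 libraries of polyclonal primary tumours came from 3 animals, so the subclone libraries of each animal were summed. The 2 runs of each single-cell group shared their barcodes, so both were averaged over the barcodes found in both, giving 1 library for each group.

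Counts were scaled by TMM, genes were kept by filterByExpr and groups were compared with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Errors of log2 changes were taken from the F statistic. The fits were tested on simulated data: at an 8-fold change they recovered 0% of the changed genes in tumour cell comparisons other than lung against primary (31.8%), 4.55% to 25.8% in stroma and 39.4% to 68.2% in sorted fractions. Gene lists, 17 human and 33 mouse, were fixed before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. Lists with 3 or more measured genes were ranked with camera of limma 3.58.1, with the preset correlation of 0.01 and with an estimated one. Each list was also adjusted over its own members alone.

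The rule named 4 kinds of genes: IL11, FIGF, Il11ra1, Plxdc1 and Plxdc2 where measured; the 6 largest rises and 6 largest falls among passing genes with a mean log2 CPM of 3 or more, leaving out clone-style and pseudogene-style names; up to 4 passing genes of each list by smallest p; and, where none passed, the 3 smallest p in each direction as values. Some genes that the rule names are not reported here. Named genes with 1 to 3 counts in an arm are given without a fold. Genes at 0 in an arm are given as bounds against a floor of 3 counts over the group.

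Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, each library left out in groups of 2 to 5, blocks of animals or of sample numbers, and fits without summing. After seeing the data, fits without stroma animal 4-3, stroma primary 3-2, tumour primaries 3-1 and 4-4, or 2 sorted libraries, and fits on single sequencing runs, were added. Counts of passing genes were compared with those of 100 drawn splits of the same libraries, also without tumour primaries 3-1 and 4-4 for lung against primary.

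Single cells with 200 or more genes and under 10% mitochondrial UMIs were kept, 3465 of the 3806 barcodes found in both runs. Genes seen in 3 or more cells were scaled to 10000 and logged, and 2000 variable genes, 30 principal components and 15 neighbours went into Leiden clustering at resolution 0.8 with scanpy 1.11.5 and leidenalg 0.10.2. Alternatives were resolution 1.2, 500 or more genes per cell and Scrublet doublets left out. The 23 clusters were named from marker genes, and the naming rule was set after the clusters had been seen. Comparisons of macrophage-like cells alone, of lung and blood monocyte-like cells and of a blood cluster with neutrophil and platelet genes were also added after seeing the cells. Shares carry exact binomial intervals and levels exact Poisson intervals. The planned tests of single-cell groups were not run, because each group holds 1 library, and classes with under 20 cells in a library were not compared. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.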

Results

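The samples came from mice carrying human tumours made of labelled subclones, in which some cells overexpressed IL11, a cytokine of the IL6 family, or FIGF, also called VEGFD, a growth factor for lymphatic and blood vessels. The other subclones carried markers alone (CFP, Thy1.1 or mch) and are called parental, as in the labels. Tumours of 1 subclone were labelled monoclonal and mixtures polyclonal. The cell line was named only for the sorted lung fractions: MDA-MB-468, a breast cancer line, with doxycycline (DOX) switching on IL11 and FIGF in 10% of the injected cells each, beside 80% CFP cells.

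RNA was measured in 4 sets of samples. Sorted human tumour cells gave 31 libraries: 8 from monoclonal primary tumours, 9 from the subclones of 3 polyclonal primary tumours, 12 from monoclonal lung metastases and 2 from polyclonal ones. Mouse stroma gave 62 samples, whose counts stand in 31 columns, 1 for each animal and site. These were 9 monoclonal and 3 polyclonal primary tumours, lungs of 4 IL11, 4 FIGF, 6 parental and 3 polyclonal animals, and 1 control fat pad and 1 control lung. Lung cells sorted by IL11RA, the receptor of IL11, and PLXDC, a receptor of vessel and stromal cells, gave 12 libraries, 2 for each of 3 fractions with and without DOX. CD45+ cells of blood, lung and tumour were measured cell by cell in 8 groups of 2 sequencing runs.

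Total counts ranged from 396974 to 17849077 in the tumour cell libraries, from 1464241 to 12058333 in the stroma and from 22222555 to 38887892 in the sorted fractions. Genes with 10 or more counts numbered 229 to 10820, 3531 to 12935 and 12713 to 15796. In the median tumour cell library 89.2% of all counts fell on 10 genes, against 28.1% in stroma and 6.55% in the sorted fractions. The 8 single-cell groups kept 355 to 512 cells with medians of 5992 to 10780 UMIs per cell. All intervals and floors given here cover counting error only.

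Lung stroma of IL11 animals held more neutrophil transcripts and fewer transcripts of connective tissue than lung stroma of parental animals, the comparison that asks what an IL11 subclone does to the lung. Normalised CPM are counts scaled to library totals that had first been adjusted by TMM. Mmp8, the neutrophil collagenase, rose from 56.8 ± 32.2 to 770 ± 412 normalised CPM (SD, n = 6 and 4). Its log2 change was 3.76 ± 0.751 (SE). Retnlg, a secreted protein of neutrophils, rose from 2272 ± 1433 to 27690 ± 14820, a log2 change of 3.61 ± 0.756. For both genes all 4 IL11 libraries lay above all 6 parental ones. Gsn, the actin-severing gelsolin, fell from 946 ± 355 to 91.1 ± 25.2, and Fbln1, a matrix glycoprotein, fell by 6.64 ± 1.26 on the log2 scale. The 4 IL11 libraries held 3531 to 5206 genes with 10 or more counts and the 6 parental ones 5641 to 11963. A sign of library quality thus moved with group, and drop-out of low genes may add to the falls.

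In all, 84 of 8017 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 19 higher and 65 lower. Mmp8, Retnlg, Gsn and Fbln1 each had an adjusted p of 0.0318. Scrg1 and Vsig10l rose as well, by 7.51 ± 1.60 and 4.92 ± 1.00 on the log2 scale (adjusted p = 0.0318 for each). The matrix gene Fbln2 fell by 6.46 ± 1.62, the integrin subunit Itgb1 fell by 2.55 ± 0.637 and the cytokine Il6 fell by 4.92 ± 1.18, each with an adjusted p of 0.0483. The small heat shock protein Hspb1 fell by 5.54 ± 1.28 (adjusted p = 0.0444). Genes at 0 in all 4 IL11 libraries were, against a floor of 3 counts over the group, at least 316-fold lower for the collagen Col6a1, at least 290-fold for the matrix gene Ogn and at least 240-fold for the contractile gene Cald1. The bound was 225-fold for the procollagen protease Adamts2, 92.4-fold for Inmt, 82.8-fold for the calcium pump regulator Sln and 73.4-fold for Plxdc2, a transmembrane receptor, with adjusted p from 0.0318 to 0.0483. Without both stroma libraries of animal 4-3 these bounds were 70.6-fold for Col6a1 (adjusted p = 0.0545), 131-fold for Ogn (0.0470), 79.3-fold for Cald1 (0.0516) and 43.2-fold for Adamts2 (0.0819). For Inmt, Sln and Plxdc2 they were 192-fold (0.00569), 172-fold (0.0318) and 74.0-fold (0.0516). Fbln2 (adjusted p = 0.0973), Itgb1 (0.0563) and Il6 (0.0545) also lost their calls without these libraries. Mmp8, Retnlg, Gsn, Fbln1, Scrg1, Vsig10l and Hspb1 kept theirs. With all libraries Lum, Eln and Prok2 passed as well, with 1 to 3 counts in 1 arm. Il11ra1, the IL11 receptor, had 2 counts in the 4 IL11 libraries and an adjusted p of 0.101, and Plxdc1 an adjusted p of 0.844. On the mouse genome GRCm38, Retnlg lies on chromosome 16 from 48872621 to 48874496, Mmp8 on chromosome 9 from 7558456 to 7568485 and Plxdc2 on chromosome 2 from 16356304 to 16755839.

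The neutrophil list ranked higher in IL11 lungs, with 17 of 19 genes above 0 and a median log2 change of 1.33 (camera adjusted p = 1.79e-14, adjusted p = 0.225 with an estimated correlation). Of these 19 genes, 2 rose over all genes tested and 7 adjusted over the list alone. The granule list, genes of immature neutrophils, had a median of 1.32 (adjusted p = 1.23e-06, adjusted p = 0.225 with an estimated correlation), with 1 gene rising over all genes and 4 adjusted over the list alone. The extracellular matrix list ranked lower, with 22 of 22 genes below 0 and a median of -4.05 (adjusted p = 3.31e-08, adjusted p = 0.389 with an estimated correlation). Over all genes 2 of them fell, and 18 adjusted over the list alone. The fibroblast list had a median of -4.15 (adjusted p = 4.13e-07, adjusted p = 0.389 with an estimated correlation), with 4 of 17 genes falling over all genes and 11 adjusted over the list alone. The endothelial list had 11 of 11 genes below 0 and a median of -4.55, or -3.74 with genes at 0 set to their bound (adjusted p = 1.2e-05, adjusted p = 0.225 with an estimated correlation), with 0 falling over all genes and 10 adjusted over the list alone. Lung epithelial genes were lower too, 7 of 9 with a median of -2.50 and -2.77 without 4-3, though the list was not called (adjusted p = 0.200, adjusted p = 0.687 with an estimated correlation; 0 over all genes and 0 adjusted over the list alone). The interferon response list had a median of 0.71 (adjusted p = 0.00077, adjusted p = 0.225 with an estimated correlation), with 0 genes rising over all genes and 2 adjusted over the list alone.

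The count of 84 rested on single libraries: it was 34 without IL11 animal 10-1, 3 without 10-2, 16 without 6-1 and 0 without 6-2, though none of the 84 genes changed sign. The parental lung library labelled 4-3 stood apart from the other 5, with a neutrophil list mean of 4.04 log2 CPM against 7.75 to 9.26 and no counts of Sftpc, the surfactant protein of lung epithelium, which had 0 and 1 counts in IL11 libraries 6-2 and 6-1 as well. Without both stroma libraries of that animal 38 genes passed, 31 of the 84 among them, and the matrix median was -2.03. Among other settings, RLE scaling gave 26 genes, no filter on low counts 365 and DESeq2 1091.

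**Figure D1:**
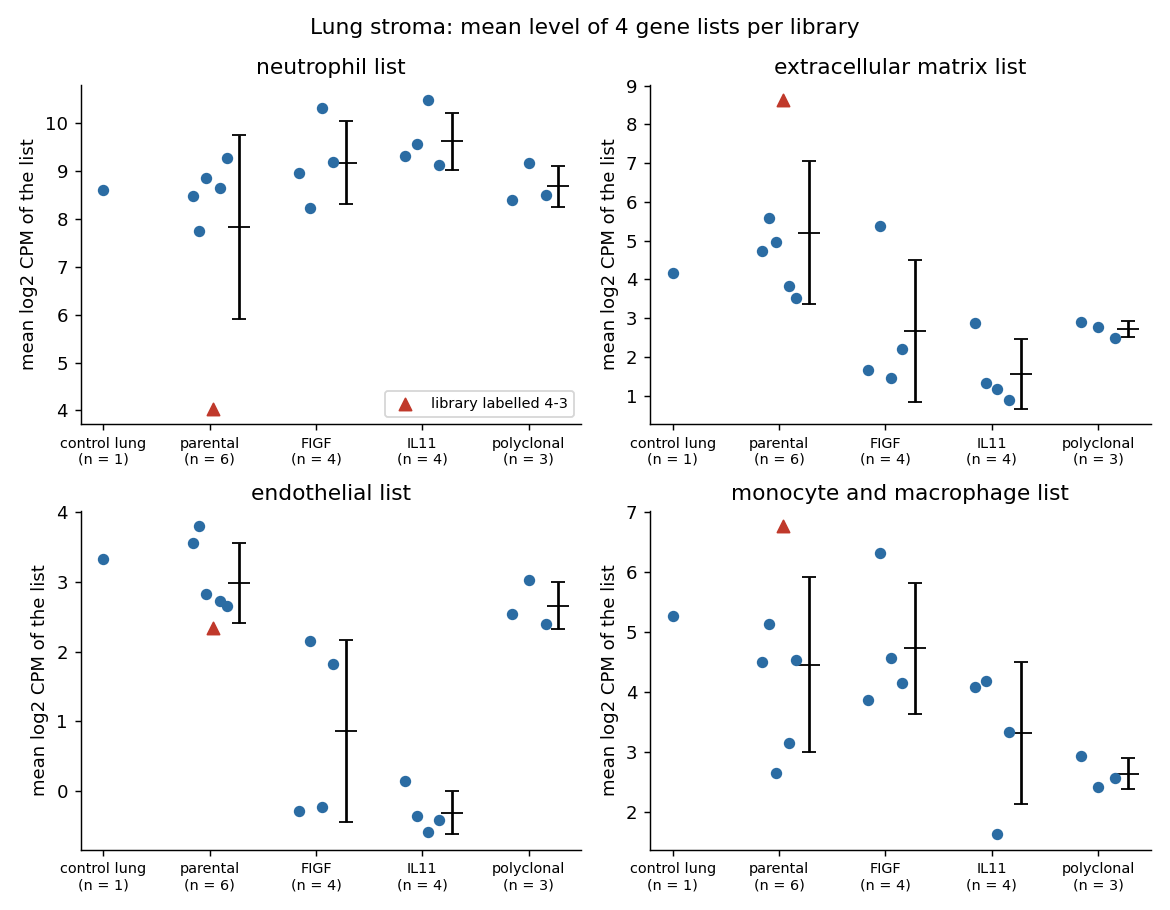
Mean log2 CPM of 4 gene lists in each lung stroma library, by group, with 1 point for each library and bars for the mean and SD; the red triangle is the parental library labelled 4-3. The 4 IL11 libraries lie between 0.880 and 2.87 on the extracellular matrix list, and the single control lung at 4.17.

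Lung stroma of FIGF animals, set against the same 6 parental libraries, showed the neutrophil list higher and the matrix list lower, without any single gene passing. The neutrophil list had 16 of 19 genes above 0 and a mean log2 change of 1.05 (camera adjusted p = 2.65e-13, adjusted p = 0.305 with an estimated correlation). All 13 genes of the granule list lay above 0, with a median of 1.23 (adjusted p = 1.91e-09, adjusted p = 0.281 with an estimated correlation). All 22 matrix genes lay below 0, with a median of -2.51 (adjusted p = 2.59e-10, adjusted p = 0.305 with an estimated correlation), and the median was -0.79 without the libraries of animal 4-3. The endothelial list had 11 of 11 genes below 0 and a median of -1.71 (adjusted p = 1.3e-05, adjusted p = 0.305 with an estimated correlation). In each of these lists 0 genes passed over all genes and 0 adjusted over the list alone.

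By edgeR's quasi-likelihood test 0 of 8017 genes passed, with 221 at an unadjusted p under 0.05 and 7 by DESeq2. Saa3, an acute phase protein, had a log2 change of 4.35 ± 0.94 (adjusted p = 0.610), the ribosomal RNA gene Rn45s 2.21 ± 0.544 and the membrane protein Tspan7 -4.82 ± 1.55 (adjusted p = 0.999 for both). Il11ra1, Plxdc1 and Plxdc2 had log2 changes of -1.88 ± 1.46, -1.49 ± 1.96 and -0.89 ± 1.21. Without FIGF animal 5-3 the count was 2, without 9-3 it was 1, and without a filter on low counts it was 2. Because both comparisons share the parental libraries, their lists are not independent of each other.

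In primary tumour stroma, the monocyte and macrophage list ranked lower in polyclonal than in monoclonal tumours, though not in every library, the comparison that asks whether a mixture of subclones changes the local microenvironment. That list had 20 of 21 genes below 0 and a median log2 change of -2.40 (camera adjusted p = 3.67e-09, adjusted p = 0.514 with an estimated correlation), with 0 genes falling over all genes and 4 adjusted over the list alone. Its library means were 3.31 to 5.60 log2 CPM in the 3 polyclonal tumours and 6.34 to 8.09 in 6 monoclonal ones, while the other 3, Thy1.1 3-1 (2.71), CFP 4-3 (3.67) and Thy1.1 3-2 (3.85), lay within or below the polyclonal range. The list of mature and activated neutrophils had 19 of 19 genes below 0 and a median of -2.07 (adjusted p = 9.64e-05, adjusted p = 0.514 with an estimated correlation), and lost its call without polyclonal animal 1-3 (adjusted p = 0.0950). Its library means overlapped, at 6.74 to 8.78 log2 CPM in polyclonal and 5.86 to 9.46 in monoclonal tumours, apart from 11.98 in the library labelled 4-3. The interferon response list had 21 of 26 genes below 0 and a median of -0.98 (adjusted p = 0.000369, adjusted p = 0.514 with an estimated correlation). The smooth muscle and pericyte list ranked higher, with 10 of 13 genes above 0 and a median of 0.73 (adjusted p = 0.00421, adjusted p = 0.514 with an estimated correlation). In the last 3 lists 0 genes passed over all genes and 0 adjusted over the list alone. The main neutrophil list was not called, with a median of -2.32 and 17 of 18 genes below 0 (adjusted p = 0.342, adjusted p = 0.781 with an estimated correlation; 0 over all genes and 0 adjusted over the list alone). Its library means were 3.18 to 4.97 log2 CPM in polyclonal and 2.28 to 4.85 in monoclonal tumours, apart from 9.13 in the library labelled 4-3. A list of epithelial genes standing in for carry-over of human tumour cells moved with the same groups, at a median of 0.59 (adjusted p = 9.64e-05, adjusted p = 0.514 with an estimated correlation).

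No single gene passed: edgeR called 0 of 12499, with 489 at an unadjusted p under 0.05, and DESeq2 called 21. The laminin Lama3 had a log2 change of 6.32 ± 1.35 and the milk casein Csn1s1 6.64 ± 1.46 (adjusted p = 0.969 for both), and the nuclear receptor coactivator Ncoa1 had -5.09 ± 1.35 (adjusted p = 0.999). Il11ra1 stood at 118 ± 4.41 against 116 ± 95.8 normalised CPM (SD, n = 3 and 9), Plxdc2 at 62.2 ± 53.4 against 43.3 ± 27.6, Figf at 30.6 ± 19.4 against 49.4 ± 30.7 and Il11 at 53.2 ± 45.5 against 84.1 ± 131. The count was 1 without the libraries of animal 4-3 and 3 with no filter on low counts.

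In lung stroma, the monocyte and macrophage list ranked lower in polyclonal than in the 14 monoclonal animals, which addresses the distant, systemic side of the same question. Library means were 2.41 to 2.93 log2 CPM in polyclonal animals, and 2 monoclonal ones lay within or below this range (IL11 6-1 at 1.62 and Thy1.1 3-1 at 2.65). That list had 18 of 19 genes below 0 and a median log2 change of -2.35 (camera adjusted p = 0.00131, adjusted p = 0.988 with an estimated correlation), with 0 genes falling over all genes and 1 adjusted over the list alone. The MHC class II list, genes of antigen presentation, had 8 of 8 below 0 and a median of -1.99 (adjusted p = 0.00411, adjusted p = 0.988 with an estimated correlation), with 0 over all genes and 1 adjusted over the list alone. It lost its call without polyclonal animal 1-1 (adjusted p = 0.0608). The endothelial list had 10 of 15 genes above 0 and a median of 0.38 (adjusted p = 0.00411, adjusted p = 0.988 with an estimated correlation), with 0 over all genes and 0 adjusted over the list alone. Its library means were 2.39 to 3.03 log2 CPM in polyclonal and 2.33 to 3.80 in parental lungs, so polyclonal lungs did not exceed parental ones. Those of IL11 (-0.585 to 0.141) and FIGF lungs (-0.286 to 2.16) were lower.

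By edgeR 0 of 9337 genes passed, with 1028 at an unadjusted p under 0.05, against 226 by DESeq2 and 48 with no filter on low counts. Ms4a4c, of the membrane-spanning 4A family, was at 0 in all 3 polyclonal libraries, at least 125-fold lower by the floor of 3 counts over the group (adjusted p = 0.447). Gpatch11 had a log2 change of 5.03 ± 1.17 (adjusted p = 0.447). Plxdc2, Il11ra1, Figf and Plxdc1 had log2 changes of -1.91 ± 1.71, -2.43 ± 1.95, -0.89 ± 1.75 and 2.49 ± 1.63. RLE scaling moved the median change of all genes by -0.109, to -0.57.

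In tumour cells, lists of ribosomal protein, hypoxia and epithelial genes ranked lower in monoclonal lung metastases than in monoclonal primary tumours, though not against every primary library. This comparison asks how the cells differ after spreading. On all 3 lists the IL11 primaries 10-1 and 10-2 lay within the lung range. Their ribosomal list means were -0.247 and -0.343 log2 CPM, against -0.746 to 1.86 in lung. SDC4, a cell surface proteoglycan, fell from 1587 ± 3573 to 0.830 ± 0.814 normalised CPM (SD, n = 8 and 12), below all primary libraries in 12 of 12. Ribosomal RPL3 fell by 6.34 ± 1.28 on the log2 scale (adjusted p = 0.00192), the glycolytic enzyme ENO1 fell by 5.02 ± 1.08 (adjusted p = 0.00247) and keratin KRT14 fell by 5.85 ± 1.62 (adjusted p = 0.0106). MXD1, a partner of MAX that opposes MYC, rose from 3.04 ± 3.87 to 917 ± 960, above all primary libraries in 8 of 12.

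By edgeR 500 of 1771 genes passed, 207 higher and 293 lower. The ribosomal protein list fell in 8 of 8 genes over all genes and adjusted over the list alone, with a median log2 change of -4.92 (camera adjusted p = 4.08e-05, adjusted p = 0.163 with an estimated correlation). Of 6 hypoxia genes all lay below 0 and 4 fell over all genes and adjusted over the list alone, among them NDRG1 by -5.39 and LDHA by -3.95, with a list median of -3.91 (adjusted p = 0.000869, adjusted p = 0.163 with an estimated correlation). Of 10 epithelial genes 4 fell over all genes and 6 adjusted over the list alone, at a median of -3.03 (adjusted p = 0.000118, adjusted p = 0.118 with an estimated correlation). Among these keratin KRT8 changed by -5.37, the desmosome protein DSP by -3.22 and the tight junction protein CLDN4 by -2.85. In the oxidative phosphorylation list 2 of 4 genes fell over all genes and adjusted over the list alone, NDUFV1 by -6.26 and ATP5B by -3.64 (adjusted p = 0.0282, adjusted p = 0.168 with an estimated correlation). The immediate early list had 2 of 4 falling over all genes and adjusted over the list alone, IER2 by -5.80 and KLF6 by -4.62 (adjusted p = 0.00656, adjusted p = 0.118 with an estimated correlation). The adhesion molecule ICAM1, the stress factor ATF4, the replication helicase subunit MCM7 and the transcription factor CEBPB fell by 5.63, 4.67, 3.78 and 1.88 on the log2 scale. The largest rises were those of TTC17, GGN, IBTK, RNF10 and CAPZA1 and the largest falls those of CUX1, LAMA4, IVNS1ABP, RPN1 and PACSIN2, each by over 8 on the log2 scale. IVNS1ABP turned upward with animals as blocks (adjusted p = 0.968) and by DESeq2 (adjusted p = 0.264).

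With the 6 animals that gave both sites as blocks, 1 gene passed in place of 500. Without the primary libraries of animals 3-1 and 4-4, which hold 10820 and 10316 genes with 10 or more counts, 233 passed. Of the 500 first calls 482 were still tested, 174 still passed and 8 changed sign. The number was 7559 with no filter and 3578 by DESeq2. The 10 highest genes took 87.7 ± 7.44% of the counts in lung libraries and 64.2 ± 28.2% in primary ones (SD, n = 12 and 8, exact permutation p = 0.00186), so a sign of library quality moved with site. GAPDH and ACTB took 4 and 1 of 3939236 counts in lung library 4-3, and 92 and 337 of 2481868 in lung library 10-2. Relative to all genes the changes depend on scaling, since RLE scaling moved the median of all genes by -0.321.

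**Figure D2:**
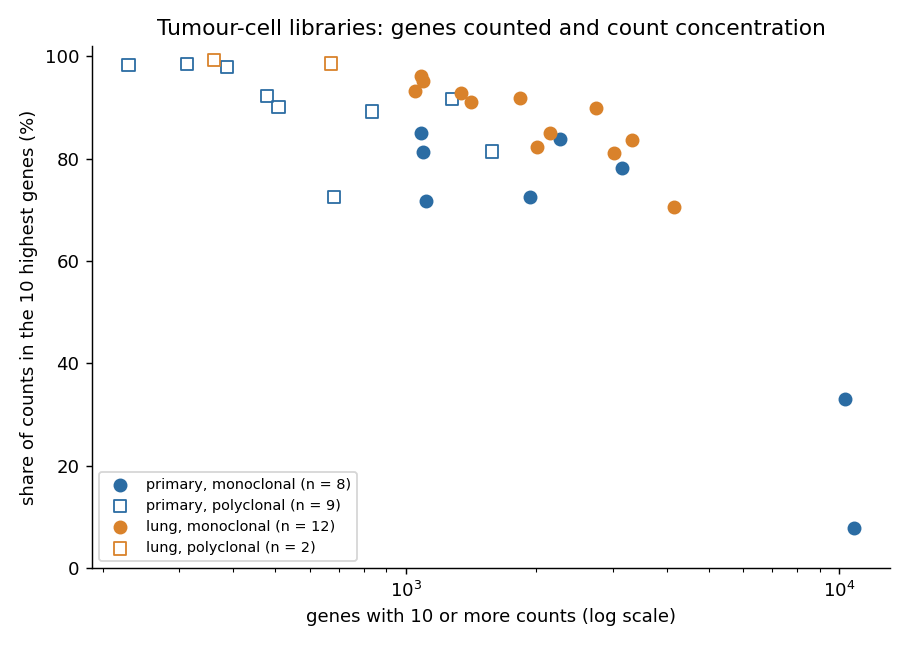
Share of all counts on the 10 highest genes (percent, vertical axis) against the number of genes with 10 or more counts (horizontal log axis) for the 31 tumour cell libraries, 1 point each, coloured by site and clonality. The shares run from 7.94% to 99.2% and the numbers of genes from 229 to 10820.

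Polyclonal and monoclonal lung metastases differed in 7 of 6962 genes by edgeR, all higher in polyclonal samples. The 7 genes were chosen for naming after their values were seen: MCC, EMC3-AS1, FBXO28, PLA2G4E, DAAM2, FBXO33 and RFNG, with log2 changes from 8.83 ± 1.68 to 17.42 ± 3.13 and adjusted p from 0.0391 to 0.0401. Each lay above all 12 monoclonal libraries in 1 of the 2 polyclonal ones. MCC, a negative regulator of the cell cycle, took 1948763 counts in the polyclonal libraries against 151 in the monoclonal ones. The list of vascular and fibroblast markers, cells that the gate could let through, was called higher with 3 genes above and 3 below 0 and a median of 0.04 (camera adjusted p = 0.0305, adjusted p = 0.126 with an estimated correlation). The median of all genes was -2.46, so the list was higher only relative to the other genes. That list held 0 genes passing over all genes and 0 adjusted over the list alone, and lost its call without animal 1-1 (adjusted p = 0.945) and without 1-4 (adjusted p = 0.308). Without animal 1-1 the log2 changes of PLA2G4E, DAAM2, FBXO33 and RFNG turned negative (adjusted p = 0.563 for each). The 7 genes became 0 without animal 1-1 and 36 without 1-4, 0 with RLE scaling, which moved the median of all genes by -0.119, and 399 by DESeq2.

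In primary tumour cells the ribosomal protein list ranked lower in polyclonal than in monoclonal samples, though not in every library. This comparison asks what subclones do to each other within a tumour. All 27 genes of the list lay below 0, at a median log2 change of -6.82, or -5.95 with genes at 0 set to their bound, while the median of all genes was -1.18 (camera adjusted p = 1.67e-10, adjusted p = 0.363 with an estimated correlation). Of these 0 fell over all genes and 22 adjusted over the list alone. The list means were -0.575 to -0.332 log2 CPM in polyclonal animals, and -0.247 and -0.343 in monoclonal IL11 primaries 10-1 and 10-2. Other monoclonal primaries stood at 1.60 to 7.45, highest in 3-1 (7.45) and 4-4 (6.66). By edgeR 0 of 5619 genes passed, with 1223 at an unadjusted p under 0.05, against 1379 by DESeq2, 114 with no filter, 1321 as a mean of contrasts within subclones and 1 without polyclonal animal 1-1. The fit with 1321 took subclone libraries of the same animal as independent, so its count rests on too many replicates. The splicing regulator MBNL2 had a log2 change of 8.86 ± 2.08 and RBM18 7.85 ± 1.69, while the translation factor EIF3A and the DNA repair protein XRCC6 were at 0 in all 3 polyclonal animals, at least 18.3-fold and 31.1-fold lower (adjusted p = 0.204 for each). RLE scaling moved the median of all genes by -0.776.

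Within IL11 cells of primary tumours 0 of 1926 genes passed by edgeR, with 103 at an unadjusted p under 0.05 and 35 by DESeq2. IL11 itself had 8 counts in 3 polyclonal libraries and 20 in 2 monoclonal ones, a log2 change of -1.69 ± 1.08. Counts of IL11 and FIGF were too low to check the subclone labels, so these cells are named by label alone. KLK2, a secreted protease, was at 0 in the polyclonal libraries and at least 136-fold lower (adjusted p = 0.858). Within FIGF cells 0 of 1926 passed by edgeR, with 248 at an unadjusted p under 0.05 and 44 by DESeq2 or when the 5 libraries of this subclone were fitted alone. The ribosomal protein list had 8 of 8 genes below 0 and a median of -5.06, or -3.86 at the bounds (camera adjusted p = 8.92e-06, adjusted p = 0.155 with an estimated correlation), with 0 falling over all genes and 6 adjusted over the list alone. RPN1, a subunit of the glycosylation complex of the endoplasmic reticulum, was at least 45.7-fold lower and the mitochondrial enzyme DLST at least 18.6-fold lower (adjusted p = 0.215 for both).

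The change from primary tumour to lung was also set between polyclonal and monoclonal animals, and 0 of 11311 genes differed by edgeR, with 1817 at an unadjusted p under 0.05 and 564 by DESeq2. The ribosomal protein list ranked higher in that difference, with a median of 4.75, or 1.72 with genes at 0 set to their bound (camera adjusted p = 3.33e-11, adjusted p = 0.314 with an estimated correlation). In it 0 genes rose over all genes and 6 adjusted over the list alone. In polyclonal animals the list means were low at both sites, -0.575 to -0.332 log2 CPM in primary tumours and -0.501 and 0.02 in lung. In monoclonal animals they were -0.343 to 7.45 in primary tumours and -0.746 to 1.86 in lung. The difference thus went with the fall in monoclonal animals, not with a clear rise in polyclonal ones. RLE scaling moved the median of all genes by 1.48.

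Among the sorted lung cells, DOX went with fewer antigen presentation transcripts and more endothelial ones in the IL11RA positive, PLXDC negative fraction, where the question is which receptor-bearing lung cells respond to tumours making IL11 and FIGF. The MHC class II list had 9 of 9 genes below 0 and a median log2 change of -1.82 (camera adjusted p = 7.13e-10, adjusted p = 0.347 with an estimated correlation), with 0 falling over all genes and 6 adjusted over the list alone. The endothelial list had 17 of 17 genes above 0 and a median of 1.00 (adjusted p = 1.37e-15, adjusted p = 0.389 with an estimated correlation), with 0 over all genes and 3 adjusted over the list alone. Its means were 9.73 log2 CPM in the DOX library G2 and 9.04 in G1, against 8.17 and 8.73 without DOX. Libraries of the other fractions without DOX reached 8.81 to 9.75, so such levels were not particular to DOX. The neutrophil list had 18 of 21 below 0 and a median of -2.38 (adjusted p = 2.81e-09, adjusted p = 0.424 with an estimated correlation), but much of that fall came from the DOX library G2. Its list mean was 2.45 log2 CPM against 5.22 in the other DOX library and 5.80 and 6.07 without DOX, and its Ptprc (CD45) 90.6 CPM against 365 to 699 in the other 3. The fibroblast list had 15 of 18 below 0 and a median of -1.44 (adjusted p = 3.51e-06, adjusted p = 0.496 with an estimated correlation). The list of VEGF receptors and ligands had 12 of 13 above 0 and a median of 0.84 (adjusted p = 2.06e-07, adjusted p = 0.347 with an estimated correlation). In these last 3 lists 0 genes passed over all genes and 0 adjusted over the list alone. Reads on no gene made up 18.3% to 26.2% of the uniquely placed reads in the 6 libraries without DOX and 8.20% to 10.9% in 4 of the 6 with DOX, the others standing at 20.3% and 21.3%.

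By edgeR 0 of 16342 genes passed in that fraction, with 867 at an unadjusted p under 0.05 and 38 by DESeq2. Tnfsf10, the death ligand TRAIL, stood at 193 ± 25.9 against 73.7 ± 11.4 normalised CPM (SD, n = 2 and 2), and Mt1, a metal-binding metallothionein, at 124 ± 4.22 against 265 ± 61.7 (adjusted p = 0.924 for both). In IL11RA negative cells 0 genes passed by edgeR, with 758 at an unadjusted p under 0.05 and 74 by DESeq2, and Mt1 stood at 101.3 ± 4.19 against 253 ± 25.5 (adjusted p = 0.936). Their MHC class II list had 9 of 9 genes below 0 and a median of -1.51 (camera adjusted p = 0.000738, adjusted p = 0.858 with an estimated correlation), with 0 over all genes and 0 adjusted over the list alone, and lost its call without the first library without DOX (adjusted p = 0.328).

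In the fraction positive for both receptors 0 genes passed by edgeR, with 272 at an unadjusted p under 0.05 and 0 by DESeq2. Il6 stood at 296 ± 287 with DOX against 27.7 ± 25.6 without (n = 2 and 2), and Rgs5, a pericyte signalling regulator, at 42.2 ± 22.9 against 12.3 ± 3.72 (adjusted p = 0.999 for both). The endothelial list had 16 of 17 genes below 0 and a median of -0.51 (camera adjusted p = 0.00271, adjusted p = 0.863 with an estimated correlation), with 0 over all genes and 0 adjusted over the list alone. It lost its call without the DOX library G2 and turned upward without the library without DOX G1, libraries that stand apart from the rest of their groups. The library without DOX G1 had a mean correlation of 0.773 with the others. The DOX library G2 was closest to the IL11RA negative library G1 without DOX (r = 0.990). Gsn stood at 16880 and 19340 normalised CPM in these 2, against 4414 in the DOX library G1. Whether the DOX label of G2 holds was not tested. Without the library without DOX G2 the count rose from 0 to 1770.

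Between fractions, Il11ra1, Plxdc1 and Plxdc2, the genes taken for the gates, differed by less than their errors, so the gates could not be seen in the RNA. The PLXDC positive library G1 without DOX went against its label, with Plxdc1 at 0.230 CPM (others 19.3 to 61.7) and the lowest Plxdc2 of the 12 libraries, 127.6 CPM. Il11ra1 had log2 differences of 0.13 ± 0.368 and 0.08 ± 0.368 in the PLXDC positive and PLXDC negative fractions against IL11RA negative cells, Plxdc1 -0.72 ± 0.842 and -0.53 ± 0.839, and Plxdc2 -0.19 ± 0.281 and -0.12 ± 0.281. Between the 2 IL11RA positive fractions Plxdc1 differed by -0.19 ± 0.838 and Plxdc2 by -0.07 ± 0.281. By edgeR 0 of 16342 genes passed in each of the 3 comparisons, with 287, 251 and 118 at an unadjusted p under 0.05 and 5, 2 and 0 by DESeq2. Plxnb2, a semaphorin receptor, had a log2 difference of -0.54 ± 0.144 between PLXDC negative and IL11RA negative cells and was lower in 4 of 4 libraries. The chemokine Ppbp of platelets had -0.66 ± 0.196 between the 2 IL11RA positive fractions, also lower in 4 of 4 (adjusted p = 1 for both). Without the PLXDC positive library G2 that had no DOX, the counts were 1020 against IL11RA negative and 975 against PLXDC negative cells.

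**Figure D3:**
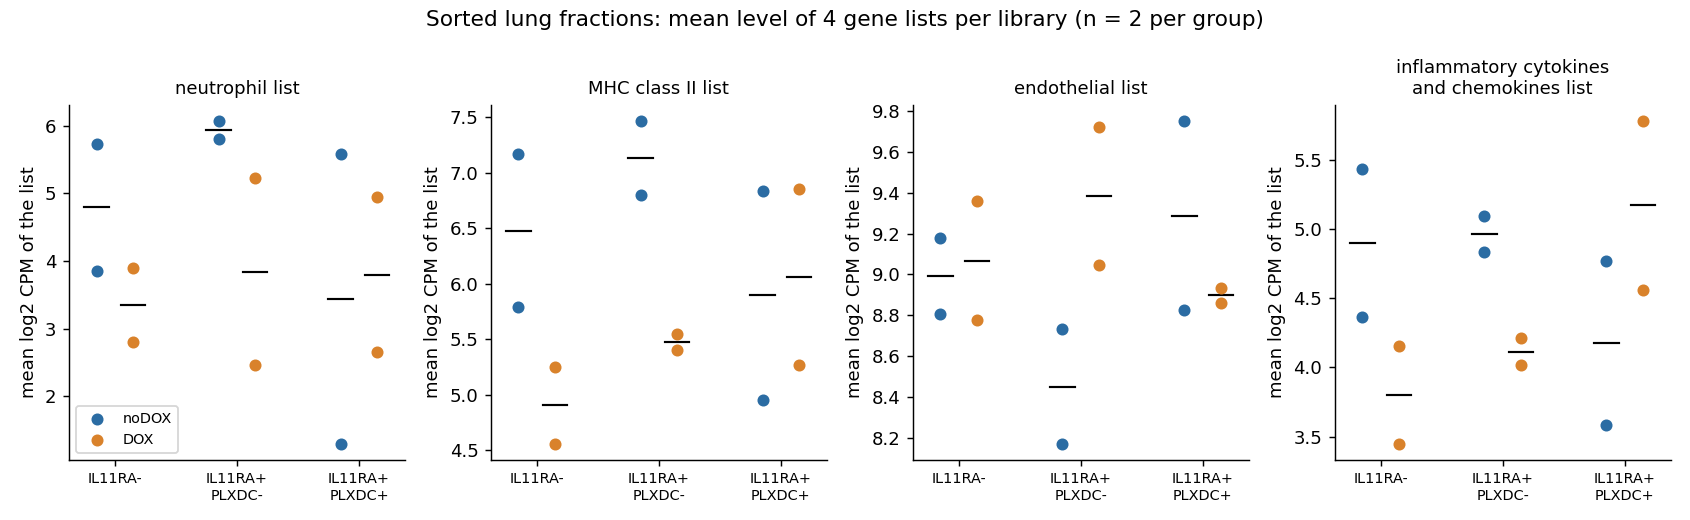
Mean log2 CPM of 4 gene lists in the sorted lung fractions, with and without DOX, with 1 point for each of the 2 libraries and a line at their mean. In the PLXDC negative fraction the MHC class II list lies at 5.41 and 5.55 with DOX and at 6.80 and 7.47 without.

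Macrophage-like cells made up 58.8% of the CD45+ cells of DOX tumours (exact 95% interval 54.4% to 63.1%, 301 of 512 cells) and 49.9% without DOX (44.5% to 55.2%, 177 of 355). The difference came with fewer cells with epithelial genes, which made up 44.8% without and 33.2% with DOX despite the CD45 gate. Among all other cells the share was 88.0% with DOX (84.1% to 91.3%) and 90.3% without (85.3% to 94.1%), so no rise of macrophages among leukocytes was seen. The shares of all cells also depended on the sequencing run, at 32.2% with and 25.1% without DOX in run 1 alone. These comparisons ask how the switch of IL11 and FIGF changes the immune cells of tumour, lung and blood, and with 1 library in each group they hold no replicates and no test. Within macrophage-like cells Cebpb, a transcription factor of myeloid cells, was 1.94-fold higher with DOX (819 against 421 CPM), and Gdf15, a stress cytokine, also 1.94-fold. Arg1, the arginine-degrading enzyme of suppressive macrophages, had 0.474 times the level without DOX (63.7 against 134 CPM), Saa3 0.515 times, the interferon gene Oasl1 0.569 times and the hypoxia gene Ndrg1 0.586 times. With DOX 1 of 19 hypoxia and glycolysis genes, 5 of 25 interferon genes and 0 of 9 MHC class II genes were higher, at median log2 ratios of -0.25, -0.26 and -0.19. Cells of the 3 clusters with neutrophil genes described below for blood numbered 0 of 355 and 0 of 512, with exact 95% intervals reaching 1.03% and 0.718%.

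In lung, alveolar macrophage-like cells made up 15.9% in naive mice (12.5% to 19.8%), 1.89% in tumour-bearing mice without DOX (0.868% to 3.56%) and 4.99% with DOX (3.15% to 7.46%). Monocyte-like cells made up 15.7%, 26.7% and 25.4%. In lung macrophage-like and monocyte-like cells together (157 with and 164 without DOX), the early growth gene Egr1 was 2.15-fold higher with DOX and Mt2, a metallothionein, 2.52-fold, with 64 of its 225.5 UMIs in 1 cell. The largest cluster of macrophage-like cells gave 41 of these cells with and 31 without DOX, and Egr1 stood at 446 and 221 CPM in it. The list of heat stress and immediate early genes, which mark handling of the cells, was higher in 13 of 15 genes (median log2 ratio 0.24), but in 8 of 15 (median 0.03) in monocyte-like cells alone. Handling and the make-up of the pooled cells may thus both add to the rise of Egr1. Folds of the matrix protein gene Spp1 and of the lipid carrier Fabp5 rested on few cells: 277.5 of 297 Spp1 UMIs without DOX came from 1 cell, and 144 of 337 Fabp5 UMIs from a cluster of 6.

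In blood, monocyte-like cells made up 25.9% in naive mice, 20.2% without and 26.6% with DOX, and these shares moved by more than their intervals in 4 of the 5 settings tried. A cluster with neutrophil and platelet genes, with a mean of 154 S100a8 UMIs per cell and Csf3r in 96.1% of its cells (1.98 and 12.8% in the erythroid-like cluster), made up 33.1%, 28.6% and 33.9%. A cluster left unnamed by the rule, with a mean of 197.8 S100a8 UMIs and Csf3r in 98.1% of its 154 cells, also carried both sets of genes and made up 13.04%, 15.3% and 8.19%. Neutrophil-like cells of a separate cluster led by granule genes made up 0.725% in naive mice, 6.40% in tumour-bearing mice without DOX (4.23% to 9.24%) and 0.443% with DOX. All 26 of these blood cells without DOX held a Camp or Ngp UMI. In lung the same cluster made up 4.16%, 1.68% and 1.13%, and 2 of 17, 3 of 8 and 1 of 5 cells held such a UMI. Compared with naive mice, blood monocyte-like cells of tumour-bearing mice without DOX had all 23 measured interferon genes higher, at a median log2 ratio of 2.15. Among them Rtp4 was 10.7-fold and Isg15, a ubiquitin-like protein induced by interferon, 8.01-fold higher. In the same cells 0 of 15 heat stress and immediate early genes were higher (median -0.87) and 14 of 14 neutrophil genes were (median 0.87). Apart from 1 naive cell of another cluster, the cells came from 2 clusters in unequal parts. These gave 81 and 25 cells in naive mice, 51 and 31 without and 47 and 73 with DOX, so handling and make-up may add to these values. Background RNA may add to the neutrophil genes, since S100a8 rose from 86.4 to 307 CPM in erythroid-like cells of the same groups and from 177 to 704 in monocyte-like cells. Lung monocyte-like cells had 19 of 19 interferon genes higher, at a median of 1.92, with the monocyte marker Ly6c2 8.02-fold and the interferon gene Ifi204 7.33-fold higher. With DOX against without, the interferon medians were -0.29 in blood monocyte-like cells and -0.13 in lung monocyte-like cells. Plxdc2 stood at 20.01 CPM in tumour macrophage-like cells with DOX (15.6 to 25.2) and 16.4 without (11.5 to 22.7), a difference not detectable at this depth.

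**Figure D4:**
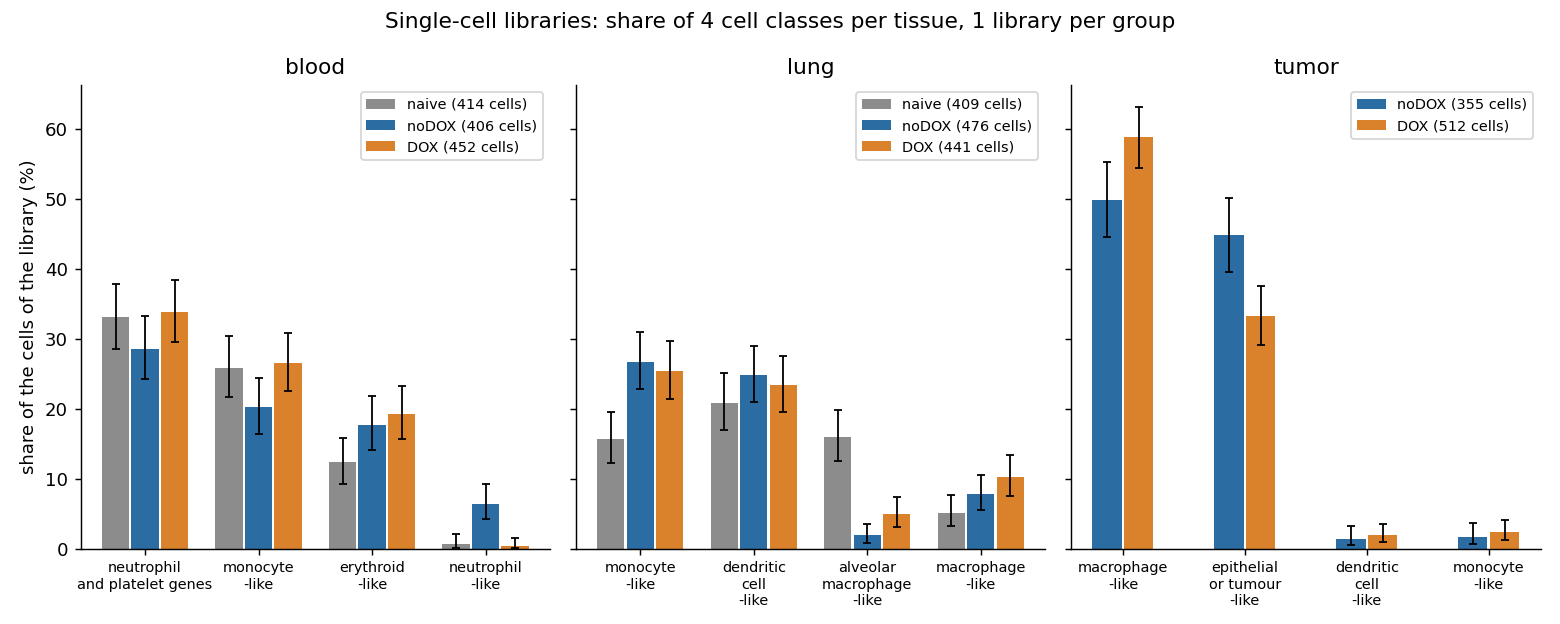
Share of kept cells (percent) in 4 cell classes for each tissue and group of the CD45+ single-cell libraries, with exact 95% intervals. Macrophage-like cells stand at 49.9% without and 58.8% with DOX in tumours, and alveolar macrophage-like cells at 15.9% in naive lungs.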

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

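Of the tests in this part, those of random gene lists and of the count without the 10 highest genes were set before their results were seen, and all others were chosen only after the result was seen. In 42 tests of a group of 4 to 10 samples, 8 values lay far from the rest, where chance gives about 1 in 20, or 2.1.

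In primary tumour stroma the CFP library labelled 4-3 had 35.3% of its counts on 10 genes (others 7.39% to 20.7%, n = 9). Its neutrophil list mean was 9.13 log2 CPM (others 2.28 to 4.85), its extracellular matrix mean 1.33 (others 7.18 to 9.20) and its fibroblast mean 0.955 (others 7.32 to 8.71). In parental lung stroma the library labelled 4-3 had 11963 genes with 10 or more counts (others 5641 to 7860, n = 6) and a neutrophil list mean of 4.04 (others 7.75 to 9.26). Both neutrophil means lie nearer to those of the other site, as after an exchange of the 2 libraries, and both were left out as an alternative. For an exchange also speak Scgb1a1, a gene of airway cells, at 87.8 CPM in the primary library (other primaries at most 6.83) and 0 in the lung library, and in the latter Il11 at 36.7 CPM (other lungs at most 1.57) and a matrix mean of 8.62, within the primary range. Yet as a parental lung the library labelled primary would have a matrix mean of 1.33 within the IL11 range (0.880 to 2.87), below the other parental lungs (3.52 to 5.59), and a fibroblast mean below every lung library (lowest 1.24). In lung stroma the FIGF library 9-1 had 12058333 counts (others 1511009 to 2755027, n = 4), and among monoclonal primary tumour cells the Thy1.1 library 3-1 had 17849077 (others 832829 to 7254214, n = 8).

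Matrix, fibroblast and endothelial genes were lower in lung stroma of IL11 than of parental animals, and 84 genes passed. As many passed in 1 of 100 splits, the real one, with 2 in the highest other. These splits argue against chance for the count, though the count fell to 0 without IL11 animal 6-2. They do not test the 3 lists, whose calls were lost with an estimated correlation. Without both 4-3 libraries the matrix median was still -2.03, which argues against an exchanged library as the whole cause, although the other 4-3 library, if a parental lung, goes against the result. The 46 genes had a median of -4.27 and none of 10000 random lists of matched expression was as low (percentile 0.01, the smallest given). Every IL11 library held fewer genes with 10 or more counts (3531 to 5206) than every parental one (5641 to 11963). The random lists cannot exclude drop-out of low genes, since genes were drawn singly and matched on a mean that includes the 4-3 lung library. There the matrix list stood at 8.62 log2 CPM, against 3.52 to 5.59 in the other parental lungs. The endothelial list was not raised there (2.33 against 2.65 to 3.80). Dilution by neutrophils alone would lower all other cells alike, yet the matrix mean fell against that of macrophages (-2.20 ± 1.03 in 4 IL11 and 0.290 ± 1.22 in 6 parental libraries, exact permutation p = 0.0143, and 0.0317 without 4-3). Macrophages are leukocytes too, so the values argue only against an even dilution of all other cells. A dilution of non-leukocytes alone cannot be excluded. The endothelial, fibroblast, matrix and lung epithelial lists all had medians below 0 (-4.55, -4.15, -4.05 and -2.50). On the difference between the matrix and macrophage means the FIGF libraries lay about as low, at -3.57 to -1.16, so this shift is not particular to IL11 lungs. An effect of the IL11 subclone may add to the pattern, but this shift cannot single it out. A different yield of stromal and epithelial cells at sorting, where epithelial genes were lower too (median -2.50), was not tested.

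Tumour cells of monoclonal lung metastases and primary tumours differed in 500 genes, as many as in 1 of 100 splits, with 194 in the highest other. These splits argue against chance for the count in a fit that ignores animals, while with 6 animals as blocks 1 gene passed. Without the primary libraries 3-1 and 4-4, 233 passed, 174 of them first calls, and 3 of 100 splits of these 18 libraries gave as many, the highest other 422, so the 2 libraries may explain much of the count. With the 10 highest genes of each library removed 309 passed, and 249 of the 253 first calls still tested stayed, which argues against a few high genes as the cause for those, and leaves the calls no longer tested open. Lung libraries held 2102 ± 1012 genes with 10 or more counts against 3972 ± 4135 (n = 12 and 8, exact permutation p = 0.162), while their 10 highest genes took more of the counts (87.7% against 64.2%, exact permutation p = 0.00186), so fewer captured transcripts cannot be told apart from a change in the cells. Metastasis itself, which the design names, stays open and untested.

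Cells with epithelial genes passed the CD45 sort of tumours. Doublets with leukocytes could be excluded as the whole cause, since at most 9.43% of these cells held a Ptprc UMI, against 87.0% and 88.7% of macrophage-like cells. Human tumour cell reads counted on mouse genes are a candidate source, since ribosomal protein pseudogenes took at least 5.96 times as many UMIs, relative to those of ribosomal protein genes, as in the other cells. No biological explanation was tested.

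In 4 comparisons the real count was 0, which each of 100 splits reaches by design (100 of 100), so these splits say nothing about chance. The highest other gave 1253 genes in primary tumour cells, 459 in primary stroma, 21 in lung stroma for polyclonal against monoclonal animals and 8 for FIGF against parental animals. Splits with so many genes point to a structure of the samples. The 2 splits of primary tumour cells that called genes (1253 and 819) both put 3-1 and 11-2 into the group of 3, and the 9 splits of primary stroma with over 100 genes each put the 4-3 or the 3-2 library there. For the 3 comparisons of sorted fractions the 18 splits are too few for a share under 0.05, with a real value of 0 and 0 in the highest other.

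With DOX 5 lists were called opposite ways in 2 fractions, the inflammatory list in 2 of the 3 pairs of fractions and the others in 1, none with all samples apart in both fractions, and the difference was not tested list by list.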

How the results depend on the processing

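Of the settings here, those that leave out stroma animal 4-3, stroma primary 3-2, tumour primaries 3-1 and 4-4 or 2 sorted PLXDC positive libraries, and those on single sequencing runs, were chosen only after the result was seen. Over all settings, list calls stayed the same in 785 cases, lost their call in 172 and reversed in 23. Calls of named genes stayed in 200, were lost in 156 and reversed in 6. Counts of genes stayed within 1.5 times in 103 cases and moved in 40, and cell shares stayed in 98 and moved in 22. The cause was not tested unless given.

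With DESeq2 the counts were 1379 (primary tumour cells), 35 (their IL11 cells), 44 (their FIGF cells), 399 (lung tumour cells), 3578 (lung against primary), 564 (difference of site changes), 21 (primary stroma), 226 (lung stroma), 1091 (IL11 lungs) and 7 (FIGF lungs). In sorted fractions it gave 5 (PLXDC positive against IL11RA negative), 2 (PLXDC negative against IL11RA negative), 74 (DOX, IL11RA negative) and 38 (DOX, PLXDC negative). Without a filter the counts were 114 in primary tumour cells, 7559 for lung against primary, 3 in primary stroma, 48 in lung stroma, 365 in IL11 and 2 in FIGF lungs. RLE scaling gave 0 in lung tumour cells and 26 in IL11 lungs. The mean of contrasts within subclones gave 1321 in primary tumour cells, with subclone libraries of the same animal taken as independent. Fitting only the 5 FIGF cell libraries gave 44. The animal block gave 1 for lung against primary, with fewer animals, and the block by sample number gave 0 in all sorted comparisons. Without primaries 3-1 and 4-4 lung against primary gave 233, and without animal 4-3 primary stroma gave 1 and IL11 lungs 38. IVNS1ABP turned upward with the block (adjusted p = 0.968) and by DESeq2 (adjusted p = 0.264), against 0.00761 by edgeR.

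Leaving out 1 library at a time gave 0 to 1 genes in primary tumour cells, 0 to 36 in lung tumour cells, 0 to 34 in IL11 and 0 to 2 in FIGF lungs. In sorted cells it gave 0 to 1020 (PLXDC positive against IL11RA negative), 0 to 975 (PLXDC positive against negative) and 0 to 1770 (DOX, PLXDC positive). Where 1 library was left in an arm, it is assumed to vary like the other groups. In lung tumour cells DAAM2, FBXO33, PLA2G4E and RFNG reversed without animal 1-1, without passing (adjusted p = 0.563 for each), and stayed higher and passed without 1-4 (adjusted p = 0.0192 for each).

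Lists that reversed in sorted cells had these ranges of camera adjusted p. For PLXDC negative against IL11RA negative: endothelial 5.88e-05 to 0.957, neutrophil 6.1e-09 to 0.632, mature neutrophil 1.15e-06 to 0.705, proliferation 4.61e-15 to 0.691. For PLXDC positive against negative: endothelial 8.28e-07 to 0.637, inflammatory 1.01e-11 to 0.926, neutrophil 6.38e-08 to 0.864, proliferation 1.04e-14 to 0.637. For PLXDC positive against IL11RA negative: inflammatory 2.8e-10 to 0.683, interferon 0.000301 to 0.845. With DOX in PLXDC positive cells: endothelial 0.000182 to 0.119, inflammatory 1.68e-09 to 0.587, mature neutrophil 4.41e-07 to 0.558. With DOX in PLXDC negative cells: granule 1.27e-10 to 0.501, tumour-associated neutrophil 7.88e-05 to 0.862, proliferation 1.47e-17 to 0.117. With DOX in IL11RA negative cells: fibroblast 1.13e-13 to 0.554, neutrophil 2.85e-06 to 0.811. Without both libraries that stand apart, 4 lists reversed: alveolar macrophage (adjusted p = 0.709) and interferon (adjusted p = 0.882) for PLXDC positive against IL11RA negative, and endothelial for PLXDC positive against negative (adjusted p = 0.751) and with DOX (adjusted p = 0.257).

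Macrophage-like cells of DOX tumours made up 53.7% at resolution 1.2, 54.0% without Scrublet doublets and 32.2% in run 1 alone, where those without DOX made up 25.1%. Blood monocyte-like cells in naive, no DOX and DOX mice made up 36.4%, 32.7% and 34.2% without Scrublet doublets, 41.8%, 41.6% and 42.2% at 500 genes, 41.8%, 38.2% and 39.8% in run 1, and 44.5%, 40.7% and 41.0% in run 2. The blood cluster with neutrophil and platelet genes made up 37.9%, 35.0% and 41.9% at 500 genes. Lung monocyte-like cells made up 23.1%, 36.2% and 32.5% in run 2.

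Not run were alternatives on the separate libraries of each stroma column, since 1 column holds both, and tests, blocks, DESeq2 and left-out libraries for single cells, with 1 library in each group. Neutrophil-like cells with granule genes were too few to compare. Tumour cell libraries held a median of 1280 genes with 10 or more counts against 7239 in stroma, at median totals of 2239552 and 2912335 counts, with 89.2% and 28.1% of them on 10 genes.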

Other observations

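The 1 control lung had a neutrophil list mean of 8.59 log2 CPM, an extracellular matrix mean of 4.17 and an endothelial mean of 3.33. Its Retnlg stood at 1757 and its Mmp8 at 154 normalised CPM. These values were scaled over all 31 stroma columns and cannot be set beside those of the IL11 and parental lungs given above. On this scale Mmp8 stood at 2.20 to 121 in parental and 463 to 1537 in IL11 lungs. Retnlg stood at 35.4 to 5741 and 21260 to 63710. S100a8, chosen after its values were seen, stood at 12970 in the control lung and 1901 in the control fat pad.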
